A study of Mus musculus with 9 samples.

How the data were processed

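RNA sequencing was performed on mouse bone marrow-derived dendritic cells (BMDCs), antigen-presenting cells grown from bone marrow, 24 h after PBS, circRNA-SIINFEKL or mRNA-OVA. Each group held 3 libraries. Per the labels, polyadenylated RNA was captured and stranded, paired-end libraries were sequenced on a NextSeq 2000 instrument.

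Per the file headers and labels, the authors aligned the reads with STAR 2.7.9a to mm39 and counted them with featureCounts of Subread 2.0.3 against GENCODE M30. The deposited values are raw counts of read pairs per gene name, for pairs with both ends aligned in the reverse-stranded orientation, without normalization. A second table from the authors holds counts for 20605 of the 55809 gene names. Its lowest row sum was 10, the highest row sum left out was 9, and 0 of its values differed from the full table. The full table was used, and gene positions were taken from it. Gene names rather than identifiers key both tables, and 17 of the 55809 names lay on several chromosomes.

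Of the 55809 names, 28024 had no count in any library. Genes were kept by filterByExpr in edgeR 4.0.16 (by group, minimum count 10), which left 15433. Libraries were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 9 libraries, with 6 residual degrees of freedom and no covariate. The 3 contrasts were circRNA-SIINFEKL against PBS, mRNA-OVA against PBS and circRNA-SIINFEKL against mRNA-OVA. All tests were two-sided. Adjusted p-values were Benjamini-Hochberg values within each contrast, and 0.05 was the threshold. The common biological coefficient of variation was 7.8%. Log2 fold changes are given with a standard error (SE), and TMM-scaled CPM as mean ± SD. The SE is approximate: it is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

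Before the data were examined, 31 gene lists with 707 entries were written down, all of which matched a gene name in the table. They covered interferon-stimulated genes, guanylate-binding proteins and immunity-related GTPases, interferon genes, RNA and DNA sensors, inflammatory and T cell-directing cytokines, chemokines, NF-kB response genes, dendritic cell maturation, MHC class I and class II presentation, cell death effectors, the integrated stress response, the unfolded protein response, cell cycle, glycolysis and hypoxia, cholesterol synthesis and uptake, lipid efflux, oxidative phosphorylation, ribosomal proteins and lysosome. Marker lists covered conventional dendritic cells of types 1 and 2, plasmacytoid dendritic cells, macrophages, monocytes, neutrophils with their precursors, mast cells with basophils and eosinophils, B cells, T and NK cells, erythroid cells and stromal cells. Some lists shared members, up to 7 between interferon-stimulated genes and sensors. Each list with at least 5 tested members was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 30 lists that qualified. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Member counts are given over all genes tested and adjusted over the list alone.

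The genes to name were also fixed beforehand. In each contrast they were the 6 largest rises and 6 largest falls among genes past the threshold with average log2 CPM of at least 2 and replicates that did not overlap. Up to 3 past-threshold members of each called list with average log2 CPM of at least 1, up to 2 past-threshold members of each other list, and a panel of immune genes were added. Predicted genes and clone names were excluded from the largest changes. Some genes that the rule names are not reported here.

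Recovery was tested on simulated data with known changes and the dispersion of these libraries. For circRNA-SIINFEKL against PBS, 76.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 12 of 15203 unchanged genes were called. For circRNA-SIINFEKL against mRNA-OVA the recoveries were 76.1%, 91% and 100%. The mRNA-OVA and PBS groups were simulated without a difference, and 1 of 15433 genes was called. None of the 30 lists simulated without a shift was called in any contrast (0 of 30 by camera). Changed genes and list members were drawn from the more abundant tested genes, so the recoveries do not cover those of lowest abundance. Fewer genes were changed than were called in the real comparisons. Genes were simulated independently, so the simulation does not cover lists whose members vary together. In circRNA-SIINFEKL against PBS the estimated correlation was 0.63 for interferon-stimulated genes and 0.78 for cell cycle.

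Total counts were compared by a two-sided exact permutation test. Principal components used log2 CPM (prior count 2) of the 1000 most variable tested genes. The overlap of the 2 contrasts with PBS was compared with independence and with 20 simulated sets in which all 9 libraries shared the PBS means.

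The alternatives chosen before the data were examined were DESeq2 1.42.0, its size factors within edgeR, library totals, upper-quartile factors, no filter on low counts, a filter at 10 CPM in 3 samples, the authors' filtered genes, limma-voom, robust dispersion, fits with only the 6 libraries compared, a fold threshold of 2, all tested genes for the principal components, the replicate number as a block, which was not run because the columns do not carry it, and leaving out each library. Totals of the filtered table were added after the data were seen. Libraries carry the running numbers 1 to 3 (PBS), 7 to 9 (circRNA-SIINFEKL) and 10 to 12 (mRNA-OVA), and these are used below. The numbers run in blocks by group, so a batch that followed them cannot be told apart from the treatments. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread among these libraries. PBS was the only control analysed here, without a carrier-alone or control-RNA group, and the treatments differ in RNA form and in encoded antigen. Analyses used R 4.3.3, and figures used Python 3.11.15 with matplotlib 3.10.9.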

Results

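The series measured gene expression in BMDCs to compare the innate immune response to a small circular RNA encoding SIINFEKL, a peptide of ovalbumin, with that to a linear mRNA encoding ovalbumin. Total counts were 18991756, 19049699 and 19115677 in the PBS libraries, 21756494, 19599965 and 21164479 after circRNA-SIINFEKL, and 19618503, 21679367 and 22326553 after mRNA-OVA. Every PBS library had fewer counts than every treated library. The exact permutation p was 0.1 for each treatment against PBS, the smallest that 3 against 3 libraries allow, and 0.7 between the treatments. The 10 most abundant genes took 6.9% to 7.5% of counts in PBS and 9.3% to 9.6% after either RNA. Mitochondrial genes took 2.6% to 4% of counts across all libraries. A count of 0 in 1 library allows up to 0.134 to 0.158 CPM, and such floors cover counting error only.

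The first principal component held 55.5% of the variance and ordered the groups from PBS through mRNA-OVA to circRNA-SIINFEKL. PBS libraries scored 23.7 to 27.4, mRNA-OVA libraries -5.2 to -1.1 and circRNA-SIINFEKL libraries -25.9 to -19.9 on it. The second component held 13.9% and set the mRNA-OVA libraries (-17.5 to -10.6) apart from both other groups. PBS libraries scored 3 to 8.5 and circRNA-SIINFEKL libraries 3.5 to 11.4 on it.

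**Figure D1:**
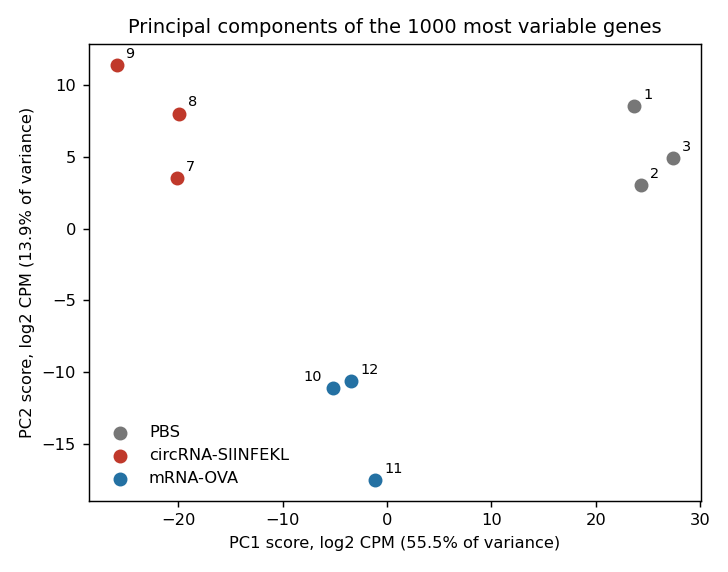
Principal component scores of the 9 libraries (log2 CPM of the 1000 most variable genes); colours mark PBS, circRNA-SIINFEKL and mRNA-OVA, and numbers are library numbers. The first axis holds 55.5% and the second 13.9% of the variance.

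The first comparison asked how BMDCs responded to circRNA-SIINFEKL relative to PBS. Inflammatory genes showed the largest rises. Marco, a scavenger receptor of macrophages, rose from 0.627 ± 0.12 to 67.4 ± 15 CPM (SD, n = 3), a log2 fold change of 6.73 ± 0.21 (SE). The neutrophil-attracting chemokines Cxcl1, Cxcl3 and Cxcl5 rose by 5.62, 4.88 and 4.65 on the log2 scale. The cytokine Tnf rose from 18 ± 0.26 to 144 ± 15 CPM and Il1b from 89.9 ± 17 to 612 ± 38 CPM (SD, n = 3). The matrix genes Postn, Col3a1 and Col1a1 were among the largest falls, at -3.61 ± 0.24, -3.09 ± 0.43 and -2.98 ± 0.24 (log2 ± SE), and Col1a1 dropped from 59.4 ± 5.4 to 7.55 ± 1.4 CPM (SD, n = 3).

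On mm39, Marco lies on chromosome 1 at 120402267 to 120432753, Cxcl1 on chromosome 5 at 91039100 to 91040974, Tnf on chromosome 17 at 35418357 to 35420983, and Col1a1 on chromosome 11 at 94827050 to 94843868. Of 15433 genes, edgeR called 4938, with 2564 higher and 2374 lower, and 512 of the former and 426 of the latter changed at least 2-fold. Scaling by library totals moved the median log2 fold change of all genes from -0.006 to -0.146. It turned the split to 1625 higher and 4428 lower of 6053, so directions are relative to the typical gene.

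Cytokine genes rose as a group (16 higher, 1 lower of 20 tested, camera adjusted p = 1.15e-27). Besides Tnf and Il1b, the members included Il1a, an alarmin (log2 fold change 4.66 ± 0.18), Il12a, a subunit of IL-12 (3.18 ± 0.26), Il6 (2.82 ± 0.19) and Il12b, the other IL-12 subunit (1.31 ± 0.14). Chemokine genes rose as well (13 higher, 3 lower of 19, adjusted p = 3.78e-12). Among NF-kB response genes, 22 of 30 were higher and 0 lower (adjusted p = 4.28e-50), including Nos2, which makes nitric oxide (3.88 ± 0.29), and Ptgs2, which makes prostaglandins (3.73 ± 0.13). The integrated stress response list rose (16 higher, 5 lower of 25, adjusted p = 4.82e-07), with Gdf15, a stress-induced cytokine (2.34 ± 0.23), Slc7a11, a cystine transporter (2.29 ± 0.09), and Cebpb, a transcription factor (1.49 ± 0.15). These 4 lists were also called with an estimated correlation (adjusted p = 0.0039, 0.041, 0.0099 and 0.011). Adjusted over the list alone, the members higher were 16, 13, 24 and 17 and those lower 1, 3, 0 and 5.

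**Figure D2:**
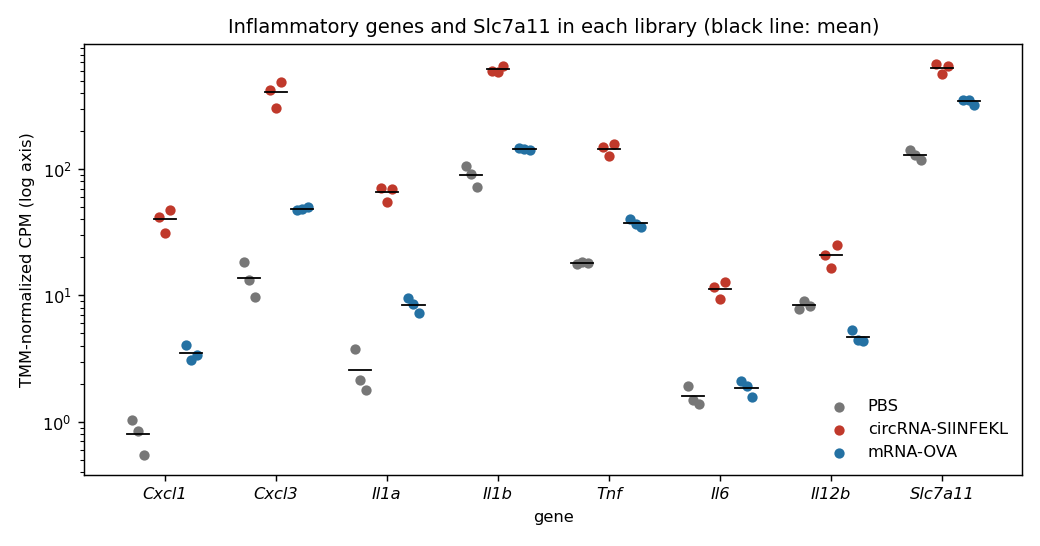
TMM-normalized CPM (log axis) of Cxcl1, Cxcl3, Il1a, Il1b, Tnf, Il6, Il12b and Slc7a11 in each of the 9 libraries, with PBS, circRNA-SIINFEKL and mRNA-OVA in separate colours and a black line at each group's mean. For Il12b the means were 8.42 in PBS, 20.9 after circRNA-SIINFEKL and 4.72 after mRNA-OVA.

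Dendritic cell maturation genes split after circRNA-SIINFEKL (14 higher, 5 lower of 28, adjusted p = 0.00537, but adjusted p = 0.33 with an estimated correlation, 16 higher and 6 lower adjusted over the list alone). Socs3 and Socs1, inhibitors of cytokine signalling, rose by 1.82 ± 0.07 and 1.73 ± 0.12, and Cd274, which encodes PD-L1, by 1.36 ± 0.09. The costimulatory genes Cd40 and Cd80 rose by 0.56 ± 0.14 and 0.42 ± 0.07, Cd86 was at 0.09 ± 0.07 (adjusted p = 0.36), and Ccr7, the receptor that guides dendritic cells to lymph nodes, fell by 0.57 (SE 0.09). MHC class II genes fell (1 higher, 12 lower of 17, adjusted p = 0.00239, adjusted p = 0.26 with an estimated correlation, 2 and 12 adjusted over the list alone). H2-Eb2 fell by 1.39, Ciita, the class II transactivator, by 0.73 and H2-Aa by 0.31, while Marchf1, a ubiquitin ligase that lowers surface class II, rose by 0.99. MHC class I genes were not called (7 higher, 1 lower of 28, adjusted p = 0.154), although H2-K1 rose by 0.27 and Cybb, a subunit of the phagocyte oxidase, by 0.96. Fry called the class I list higher (adjusted p = 0.0042). The H2-K1 call ended with library totals (adjusted p = 0.111).

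Glycolysis and hypoxia genes rose after circRNA-SIINFEKL (22 higher, 0 lower of 23, adjusted p = 1.72e-24, adjusted p = 0.056 with an estimated correlation), with Egln3, an oxygen sensor (1.59 ± 0.12), Slc2a1, a glucose transporter (1.13 ± 0.06), and Bnip3, a mitophagy receptor (1.13 ± 0.08). Cell cycle genes fell (0 higher, 36 lower of 38, adjusted p = 4.93e-27, adjusted p = 0.17 with an estimated correlation), among them the mitotic genes Kif11 (-1.16 ± 0.11), Aurka (-1.14 ± 0.10) and Cenpe (-1.14 ± 0.12). Cholesterol synthesis genes fell (0 higher, 18 lower of 23, adjusted p = 1.89e-10, adjusted p = 0.076 with an estimated correlation), with Mvk at -0.71 and Cyp51 at -0.69. Lysosomal genes rose (20 higher, 3 lower of 30, adjusted p = 1.55e-05, adjusted p = 0.24 with an estimated correlation), including Gpnmb (1.08), Atp6v0d2, a proton pump subunit (1.06), and Cd68 (0.83). Cell death effectors rose (9 higher, 2 lower of 23, adjusted p = 0.0191, adjusted p = 0.10 with an estimated correlation), with Ninj1, which ruptures the membrane of dying cells (0.92), Tnfrsf10b (0.91) and the death receptor Fas (0.88). That list's call ended with library totals (adjusted p = 0.073). Adjusted over the list alone, the higher and lower members were 23 and 0 for glycolysis, 1 and 36 for cell cycle, 0 and 19 for cholesterol, 21 and 3 for lysosome, and 11 and 2 for cell death.

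Interferon-stimulated genes were not called as a list after circRNA-SIINFEKL (10 higher, 11 lower of 55, adjusted p = 0.856, 11 and 11 adjusted over the list alone). Their median log2 fold change was 0.09, their mean -0.05 and the camera direction down, and the median turned to -0.05 with library totals. Isg15 was at 0.22 ± 0.20, Ifit1 at -0.43 ± 0.30 and Cxcl10 at -0.47 ± 0.31, none past the threshold. Ifit1bl1 fell by 1.63 (SE 0.28) and Ifit3b by 1.81 (SE 0.50), the latter with adjusted p = 0.0549 without library 9, and counts are uncertain between paralogs that share sequence. Sensor genes were not called (8 higher, 2 lower of 30, adjusted p = 0.409). Ddx58, which encodes RIG-I, was at 0.22, Ifih1, which encodes MDA5, at 0.09 and Eif2ak2, which encodes PKR, at 0.21, none past the threshold, while Tlr7 rose by 0.56, Ikbke by 0.70 and Sting1 fell by 0.78. Tlr3 was at -0.51 and Tlr8 at -0.25, and both passed with library totals (adjusted p = 0.0282 and 0.006), as did Tlr8 without library 3 or 7 (adjusted p = 0.0217 and 0.0274) and Eif2ak2 without library 12 (adjusted p = 0.0254). Zbp1, a sensor of Z-form nucleic acid, rose by 0.49, a call that ended without library 8 or 9 (adjusted p = 0.0546 and 0.0611) and with library totals (adjusted p = 0.0621). Guanylate-binding proteins and immunity-related GTPases were not called (1 higher, 5 lower of 16, adjusted p = 0.119).

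Interferon genes themselves were near the floor and none of the 21 was tested. Over the 3 libraries of a group they summed to 2 counts in PBS, 2 after circRNA-SIINFEKL and 3 after mRNA-OVA, of which Ifnb1 held 1, 1 and 3. No difference in interferon transcripts was detectable at this depth. Csf3, which encodes G-CSF and was singled out after its values were seen, had 0 counts in PBS, 184 after circRNA-SIINFEKL and 4 after mRNA-OVA. It was at least 56.1-fold higher after circRNA-SIINFEKL than a floor of 3 counts over the PBS group.

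Markers of other cell types also moved in circRNA-SIINFEKL libraries. Stromal genes fell (0 higher, 8 lower of 11, 9 lower adjusted over the list alone, median -2.29, adjusted p = 3.59e-13, adjusted p = 0.056 with an estimated correlation). T and NK cell genes fell (0 higher, 4 lower of 7, the same adjusted over the list alone, adjusted p = 0.0191, adjusted p = 0.12 with an estimated correlation), with Klrd1 at -1.27, Nkg7 at -0.83 and Cd3g at -0.73, a list whose call ended with library totals (adjusted p = 0.073). The calls of Nkg7 and Cd3g ended without libraries 2 and 3 (adjusted p = 0.0943 and 0.0612). Neutrophil and precursor markers were not called (10 higher, 5 lower of 22, adjusted p = 0.627), with Mpo, a granule enzyme of early precursors, at -1.97 and Lcn2 at 1.25. Macrophage markers split (6 higher, 6 lower of 16, adjusted p = 0.505), with Pf4 at 1.38 and Cd14 at 1.36. Monocyte (4 higher, 4 lower of 13), type 1 (3 and 3 of 10), type 2 (6 and 5 of 13) and plasmacytoid dendritic cell markers (2 and 3 of 8) were not called (adjusted p = 0.627, 0.797, 0.856 and 0.333). Dpp4 fell by 1.03 and Flt3, a dendritic cell growth factor receptor, by 0.98. Mast cell (4 higher, 2 lower of 14), B cell (2 and 2 of 7) and erythroid markers (1 and 1 of 5) were not called either (adjusted p = 0.532, 0.456 and 0.749).

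After circRNA-SIINFEKL, oxidative phosphorylation had 1 gene higher and 0 lower of 29 and ribosomal proteins 0 higher and 2 lower of 39 (adjusted p = 0.934 and 0.799), with medians of 0.01 and 0.06 that turned to -0.13 and -0.08 with library totals. The unfolded protein response had 8 higher and 2 lower of 20 (adjusted p = 0.0606), and was called without library 3 (adjusted p = 0.0058). Lipid efflux genes had 4 higher and 5 lower of 12 (adjusted p = 0.799), with median 0.02, mean -0.12 and the camera direction up, and among them Abca1, a cholesterol exporter, rose by 1.18 and Apoc1 fell by 2.35. Actb was at 0.04 ± 0.08, which turned to -0.10 with library totals, and Gapdh, a glycolytic gene, rose by 0.55 ± 0.07. Arg1 rose by 0.79 ± 0.28, but its call ended without library 1, 3, 7, 8 or 9 (adjusted p = 0.125, 0.159, 0.101, 0.0596 and 0.0806) and with library totals (adjusted p = 0.0778).

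The second comparison asked how BMDCs responded to mRNA-OVA relative to PBS. Ptgs2 rose from 3.19 ± 0.38 to 18.2 ± 2.6 CPM (SD, n = 3), a log2 fold change of 2.51 ± 0.13 (SE). Ccn3, a matricellular protein, Wnk2, a kinase, Cck, a peptide hormone, Cxcl1 and Grem1, a BMP antagonist, rose by 2.61, 2.52, 2.12, 2.11 and 2.02. Postn, the actin gene Acta2, the class II gene H2-Eb2, Lad1, Sult1a1 and Cx3cr1, a chemokine receptor, showed the largest falls, at -2.07, -2.03, -1.96, -1.80, -1.77 and -1.73. Acta2 went from 40.3 ± 4.5 to 9.87 ± 0.44 CPM (SD, n = 3). Tnf rose by 1.04 ± 0.09 and Il1b by 0.68 ± 0.10, whereas Il12b fell by 0.84 (SE 0.16) and Cd40 by 0.65 (SE 0.15).

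On mm39, Ptgs2 lies on chromosome 1 at 149975782 to 149983978, Ccn3 on chromosome 15 at 54609098 to 54617435 and Acta2 on chromosome 19 at 34218490 to 34232990. Of 15433 genes, edgeR called 3861, with 2113 higher and 1748 lower, and 318 and 233 of these changed at least 2-fold. Library totals moved the median of all genes from -0.004 to -0.116 and turned the split to 1355 higher and 3292 lower of 4647.

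Cytokine genes rose after mRNA-OVA (12 higher, 1 lower of 20, the same adjusted over the list alone, adjusted p = 5.67e-11, 0.025 with an estimated correlation), led by Il1a (1.71 ± 0.21), Il1rn, the antagonist of the IL-1 receptor (1.12 ± 0.06), and Lif (1.09 ± 0.13), with Il6 at 0.22 ± 0.23 (adjusted p = 0.533). The integrated stress response rose (13 higher, 2 lower of 25, with 13 and 4 adjusted over the list alone, adjusted p = 3.9e-06, 0.025 with an estimated correlation), with Gdf15 (1.89), Slc7a11 (1.4) and Trib3, a pseudokinase (1.27). NF-kB response genes rose (17 higher, 3 lower of 30, with 17 and 6 adjusted over the list alone, adjusted p = 3.29e-06, adjusted p = 0.19 with an estimated correlation), including Slc7a2, an arginine transporter (1.92), and Marco (1.62). Chemokines split (8 higher, 6 lower of 19, with 8 and 7 adjusted over the list alone, adjusted p = 0.0392, adjusted p = 0.42 with an estimated correlation), with Cxcl3 at 1.82 and Cxcl2 at 1.68. The chemokine call ended without library 2, 3, 7 or 10 (adjusted p = 0.05, 0.078, 0.05 and 0.065).

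Interferon-stimulated genes rose after mRNA-OVA (25 higher, 5 lower of 55, with 29 and 6 adjusted over the list alone, median 0.34, adjusted p = 0.000258, adjusted p = 0.66 with an estimated correlation). Rtp4 rose by 1.36 ± 0.33, Phf11d by 1.25 ± 0.23 and Rsad2, an antiviral enzyme, by 1.17 ± 0.28. The libraries differed: list medians against the PBS mean were 0.52, 0.51 and -0.01 in libraries 10, 11 and 12, and Rsad2 stood at 19.6, 20.7 and 7.12 CPM. Without library 10 or 11, 15 members were higher, and without library 12, 36 were. Isg15 rose by 0.58 (adjusted p = 0.0419), a call that ended without any of libraries 1, 2, 3, 9, 10 and 11 (highest adjusted p = 0.239) and with library totals (adjusted p = 0.0923), while Ifit1 (0.53) and Cxcl10 (0.55) passed only without library 12 (adjusted p = 0.00615 and 0.00709). Sensor genes rose (11 higher, 2 lower of 30, with 13 and 3 adjusted over the list alone, adjusted p = 0.0393, adjusted p = 0.46 with an estimated correlation), with Oas3 (1.01), Irf7 (0.98), Zbp1 (0.76), Tlr7 (0.72) and Ddx58 (0.53). That call ended with library totals (adjusted p = 0.13) and without library 1, 3, 10 or 11 (adjusted p = 0.056, 0.071, 0.095 and 0.11). Eif2ak2 rose by 0.34, with its call ended by library totals and without library 1, 10 or 11 (adjusted p = 0.105, 0.0561, 0.0901 and 0.133), and Ifih1 was at 0.25 (adjusted p = 0.0598), past the threshold without library 12 (adjusted p = 0.00336). Guanylate-binding proteins and immunity-related GTPases were not called (3 higher, 1 lower of 16, adjusted p = 0.506), with Igtp at 0.55.

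MHC class II genes fell after mRNA-OVA (2 higher, 10 lower of 17, the same adjusted over the list alone, adjusted p = 2.82e-05, adjusted p = 0.13 with an estimated correlation), with Ciita at -0.63, H2-Ab1 at -0.58 and H2-Aa at -0.39. MHC class I genes were not called (9 higher, 1 lower of 28, adjusted p = 0.0805, called without library 3, adjusted p = 0.049), although H2-T24 rose by 1.21 and Cybb by 0.60, with H2-K1 at 0.13 (adjusted p = 0.154). Fry called the class I list higher (adjusted p = 0.0074). Maturation genes were not called (5 higher, 8 lower of 28, adjusted p = 0.506), with Fscn1, an actin-bundling protein of mature dendritic cells, at -1.35, Ccr7 at -0.76 and Socs1 at 0.88, and neither Cd80 (0.09) nor Cd86 (0.07) passed.

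Metabolic and growth lists moved in mRNA-OVA cells as follows. Glycolysis and hypoxia genes rose (21 higher, 1 lower of 23, adjusted p = 1.98e-15, adjusted p = 0.12 with an estimated correlation), with Egln3 (1.11), Vegfa, an angiogenic factor (0.89), Bnip3 (0.78) and Gapdh (0.36). Cell cycle genes fell (0 higher, 33 lower of 38, adjusted p = 4.36e-25, adjusted p = 0.17 with an estimated correlation), with Birc5 (-1.01), Cdc20 (-1) and Ccnb2 (-0.96). Cholesterol genes fell (0 higher, 21 lower of 23, adjusted p = 1.46e-16, adjusted p = 0.055 with an estimated correlation), with Fdps (-0.76) and Idi1 (-0.75). Lysosomal genes rose (21 higher, 2 lower of 30, adjusted p = 5.67e-11, adjusted p = 0.12 with an estimated correlation), with Atp6v0d2 (1.62), Gpnmb (1.15) and the protease Ctsl (0.74). Cell death effectors rose (12 higher, 2 lower of 23, adjusted p = 0.0184, adjusted p = 0.12 with an estimated correlation), with Gsdme, a pore-forming gasdermin (0.67), and Tnfrsf10b (0.63), a call ended by library totals (adjusted p = 0.061). Adjusted over the list alone, the higher and lower members were 21 and 1 for glycolysis, 0 and 34 for cell cycle, 0 and 22 for cholesterol, 24 and 2 for lysosome, and 13 and 2 for cell death. Not called were lipid efflux (3 higher, 3 lower of 12), oxidative phosphorylation (0 and 1 of 29), ribosomal proteins (0 and 0 of 39) and the unfolded protein response (7 and 1 of 20), with adjusted p = 0.679, 0.526, 0.526 and 0.116. The unfolded protein response passed without library 3 (adjusted p = 0.014). Actb was at 0.00 ± 0.08.

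Among cell type markers, stromal genes fell after mRNA-OVA (0 higher, 6 lower of 11, the same adjusted over the list alone, median -1, adjusted p = 1.86e-08, adjusted p = 0.12 with an estimated correlation), with Col1a1 at -1.67 and Col1a2 at -1.58. Library medians were -1.45, -0.48 and -1.25 in libraries 10, 11 and 12. Plasmacytoid dendritic cell markers fell (1 higher, 3 lower of 8, 4 lower adjusted over the list alone, adjusted p = 0.0184, adjusted p = 0.13 with an estimated correlation), with Cd300c (-1.43) and the transcription factor Spib (-0.90). T and NK cell markers fell (0 higher, 2 lower of 7, the same adjusted over the list alone, adjusted p = 0.0184, adjusted p = 0.13 with an estimated correlation), with Klrd1 at -1.21, and that call ended with library totals (adjusted p = 0.061). Macrophage markers rose (7 higher, 2 lower of 16, 9 higher adjusted over the list alone, adjusted p = 0.00759, adjusted p = 0.17 with an estimated correlation), with Pf4 (1.02) and Mrc1, the mannose receptor (0.45). Mast cell, basophil and eosinophil markers rose (8 higher, 2 lower of 14, 9 higher adjusted over the list alone, adjusted p = 0.00759, adjusted p = 0.40 with an estimated correlation), with the transcription factor Gata1 (1.5) and the protease Cpa3 (0.80). Neutrophil and precursor markers rose as a list (12 higher, 4 lower of 22, with 12 and 5 adjusted over the list alone, adjusted p = 0.0289, adjusted p = 0.73 with an estimated correlation), with Mpo at -1.43, Lcn2 at 1.05 and the collagenase Mmp8 at 1.02, and the call ended without library 1 or 12 (adjusted p = 0.29 and 0.12). Monocyte (3 higher, 3 lower of 13), type 1 (3 and 2 of 10) and type 2 dendritic cell (7 and 4 of 13), B cell (1 and 2 of 7) and erythroid markers (1 and 2 of 5) were not called, with adjusted p = 0.526, 0.679, 0.526, 0.139 and 0.526. Median, mean and camera direction differed in sign for type 1 markers (-0.16, 0.01, up), type 2 markers (0.25, -0.16, down) and erythroid markers (0.77, 0.33, down).

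**Figure D3:**
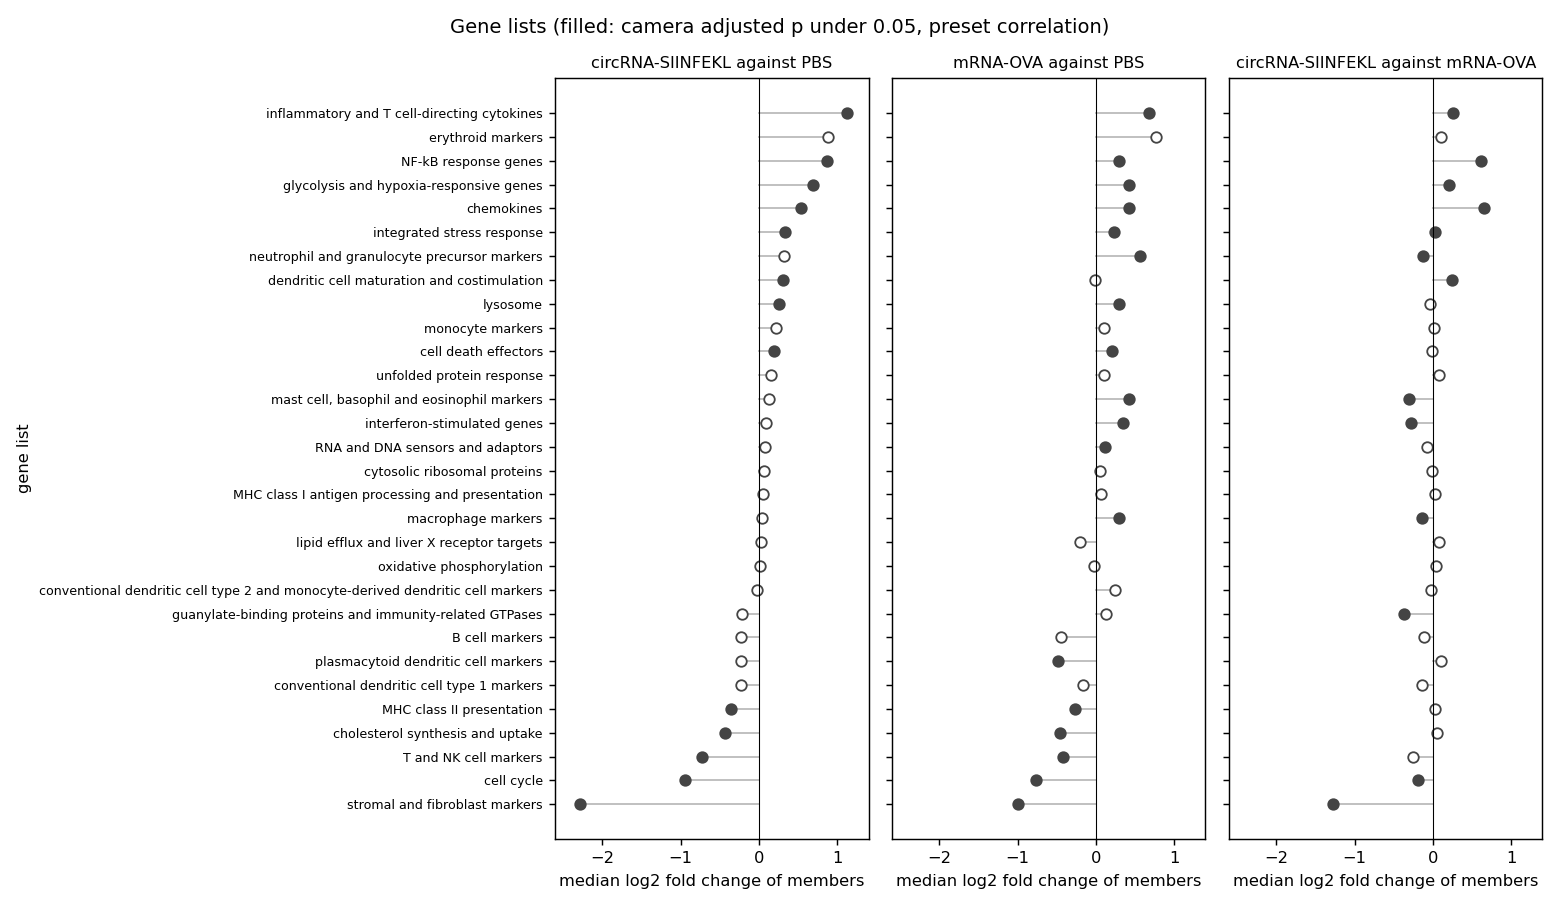
Median log2 fold change of the tested members of 30 gene lists in the 3 comparisons; filled points had a camera adjusted p under 0.05 at the preset correlation. With library totals, 12 medians of unfilled points in the comparisons with PBS changed sign, while no filled point did.

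Both responses shared most of their direction. Of the genes called in both contrasts with PBS, 1657 were higher in both and 1412 lower in both, against 351 and 269 under independence, and 12 went opposite ways. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.785 and a covariance of 0.2. The same 3 PBS libraries stand in both contrasts, and 20 simulated sets without any effect gave a median overlap of 0 (highest 1), a correlation of 0.5 and a covariance of 0.024. Those sets had a median of 0 genes called for circRNA-SIINFEKL against PBS. Their overlap therefore cannot show how much shared controls add when many genes change. With 3 PBS libraries the controls cannot be divided between the contrasts with at least 2 in each, so part of the excess may come from the shared controls.

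The third comparison asked how the responses to the RNAs differed. Inflammatory genes were higher after circRNA-SIINFEKL than after mRNA-OVA. Marco stood at 67.4 ± 15 against 1.94 ± 0.32 CPM (SD, n = 3), a log2 difference of 5.11 ± 0.17 (SE). Cxcl5, Cxcl1, the acute-phase gene Saa3, Cxcl3 and Il1a were higher by 4.23, 3.52, 3.18, 3.06 and 2.95. Il6, Il12a, Il12b, Il1b and Tnf were higher by 2.60, 2.50, 2.15, 2.09 and 1.96, and Il12b stood at 20.9 ± 4.3 against 4.72 ± 0.52 CPM (SD, n = 3). Among the genes that were lower were Postn (-1.53 ± 0.28), a matrix gene, and Ifit2 (-1.16 ± 0.19), an interferon-stimulated gene.

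**Figure D4:**
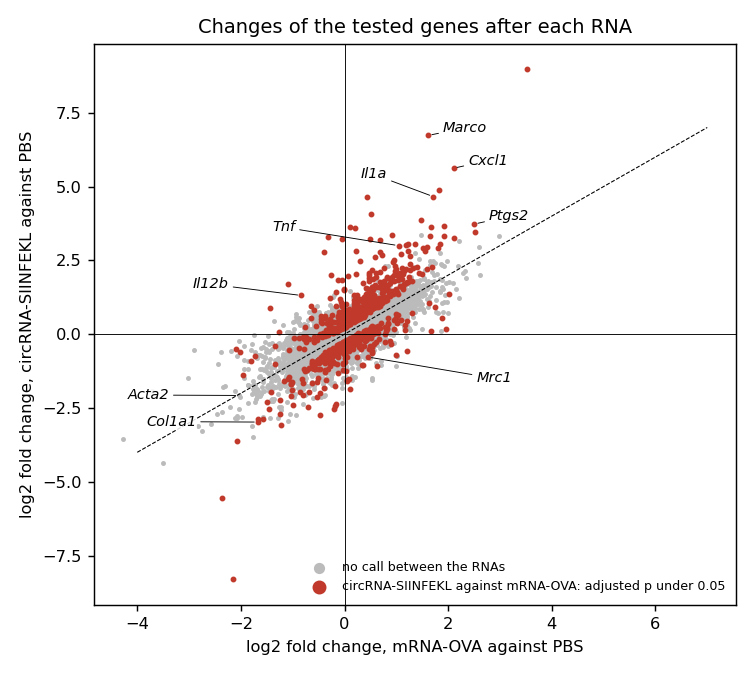
Log2 fold change of each tested gene after mRNA-OVA (horizontal) and circRNA-SIINFEKL (vertical) against PBS, with genes called between the RNAs in red and the line of equal change dashed. Csf3, the highest point, had 0 counts in PBS, and Prss23, the lowest, had 0 counts after circRNA-SIINFEKL, so their plotted values depend on the fit.

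On mm39, Cxcl5 lies on chromosome 5 at 90907219 to 90909483, Il12b on chromosome 11 at 44290890 to 44304860 and Ifit2 on chromosome 19 at 34528094 to 34553819. Of 15433 genes, edgeR called 861, with 505 higher and 356 lower after circRNA-SIINFEKL, and 99 and 49 of these differed at least 2-fold. Without library 9, 490 were called (338 higher, 152 lower), and without library 11, 580 (414 higher, 166 lower).

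NF-kB response genes were higher after circRNA-SIINFEKL (25 higher, 0 lower of 30, adjusted p = 6.89e-107), as were chemokines (10 higher, 3 lower of 19, adjusted p = 2.16e-27) and cytokines (8 higher, 1 lower of 20, adjusted p = 3.75e-30). All 3 were called with an estimated correlation (adjusted p = 0.0017, 0.0077 and 0.0017), and adjusted over the list alone 27, 11 and 9 members were higher and 0, 4 and 4 lower. Nos2 was higher by 2.40 ± 0.25. Maturation genes were higher (11 higher, 0 lower of 28, the same adjusted over the list alone, adjusted p = 3.01e-12, adjusted p = 0.059 with an estimated correlation), with Cd40 (1.21), Socs3 (1.06), Socs1 (0.85) and Cd80 (0.33), while Cd86 was at 0.02 and Ccr7 at 0.18. The integrated stress response was higher (4 higher, 2 lower of 25, with 8 and 2 adjusted over the list alone, adjusted p = 0.0132, adjusted p = 0.12 with an estimated correlation), with Slc7a11 (0.89), Cebpb (0.70) and Slc3a2 (0.53), a call ended without library 10 (adjusted p = 0.06). Glycolysis and hypoxia genes were higher (10 higher, 0 lower of 23, 18 higher adjusted over the list alone, adjusted p = 1.23e-12, adjusted p = 0.18 with an estimated correlation), with Slc2a1 at 0.50.

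Interferon-stimulated genes were lower after circRNA-SIINFEKL than after mRNA-OVA (0 higher, 6 lower of 55, 11 lower adjusted over the list alone, median -0.28, adjusted p = 2.02e-09, adjusted p = 0.51 with an estimated correlation). Ifit3 differed by -1.38, Ifit2 by -1.16 and Rsad2 by -1.03. The Ifit3 call ended without library 10 or 11 (adjusted p = 0.0554 and 0.0694) and that of Rsad2 without library 7, 9, 10 or 11 (adjusted p = 0.0981, 0.163, 0.155 and 0.195) and in DESeq2 (adjusted p = 0.122). In turn, Ifit1 (-0.96) and Cxcl10 (-1.02) had adjusted p = 0.0653 and 0.0568 in edgeR and 0.0143 and 0.0153 in DESeq2, and both passed without library 12 (adjusted p = 0.00125 and 0.00134), Ifit1 also without library 8 and Cxcl10 without library 1 (adjusted p = 0.0453 and 0.0454). Without library 10 or 11, 1 member was lower, without library 7 or 9, 3, without library 8, 10, and without library 12, 29. The list median went to -0.15 without library 10 and to -0.43 without library 12. Guanylate-binding proteins and immunity-related GTPases were lower (1 higher, 6 lower of 16, 10 lower adjusted over the list alone, adjusted p = 5.89e-06, adjusted p = 0.40 with an estimated correlation), with Gbp9 at -0.93 and Gbp8 at -0.81. Against the PBS mean, that list's medians were 0.3, 0.25 and -0.17 in libraries 10, 11 and 12. Library 12 thus lay among the circRNA-SIINFEKL libraries (-0.24, -0.12 and -0.31). Sensors were not called (1 higher, 1 lower of 30, adjusted p = 0.33), but passed without library 12 (adjusted p = 0.0072), as did Ddx58, which was at -0.30 with all libraries and at -0.44 without library 12 (adjusted p = 0.016).

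Stromal genes were lower after circRNA-SIINFEKL than after mRNA-OVA (0 higher, 7 lower of 11, the same adjusted over the list alone, median -1.28, adjusted p = 1.61e-08, adjusted p = 0.14 with an estimated correlation). Sparc differed by -1.39 ± 0.27 and Col1a2 by -1.28 ± 0.19. Col6a2 (-2.28), Col3a1 (-1.87), Igfbp5 (-1.63) and Col6a1 (-1.43) rested on few libraries: without library 9 their adjusted p was 0.0824, 0.111, 0.09 and 0.198, and without library 11 Col3a1, Igfbp5 and Col6a1 were at 0.0762, 0.128 and 0.279. In DESeq2 these 3 genes also missed the threshold (adjusted p = 0.0517, 0.061 and 0.123). Col6a1 also missed the threshold without library 2, 3, 7 or 8 (adjusted p = 0.0529, 0.0515, 0.0556 and 0.0969). Without either library 3 members were lower. Mamdc2 differed by -1.39.

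Macrophage markers were lower as a list (3 higher, 5 lower of 16, with 4 and 8 adjusted over the list alone, adjusted p = 0.0309, adjusted p = 0.40 with an estimated correlation), with Mrc1 at -1.22, Mertk, a receptor for dying cells, at -0.75 and Cd14 at 0.91, and the call ended without library 1, 3, 8 or 11 (adjusted p = 0.053, 0.06, 0.23 and 0.057). Neutrophil and precursor markers (0 higher, 1 lower of 22, 3 lower adjusted over the list alone, adjusted p = 0.0442, adjusted p = 0.74 with an estimated correlation) and mast cell markers (0 and 0 of 14, the same adjusted over the list alone, adjusted p = 0.0155, adjusted p = 0.51 with an estimated correlation) were lower as lists. The neutrophil call ended without library 3, 7, 9, 11 or 12 (adjusted p = 0.056, 0.73, 0.092, 0.086 and 0.29) and the mast cell call without library 7 or 11 (adjusted p = 0.17 and 0.057). Cell cycle genes were lower (0 higher, 2 lower of 38, 4 lower adjusted over the list alone, median -0.19, adjusted p = 4.93e-06, adjusted p = 0.59 with an estimated correlation). Its members past the threshold, Cdc6 (-0.48, adjusted p = 0.0458) and Mcm6 (-0.33, adjusted p = 0.0444), missed it without any 1 of libraries 2 and 7 to 12, with highest adjusted p = 0.176 and 0.2, and Cdc6 missed it in DESeq2 (adjusted p = 0.0517).

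Lists not called between the RNAs were MHC class I (1 higher, 2 lower of 28, adjusted p = 0.755) and class II (2 and 3 of 17; 0.755), cell death (5 and 0 of 23; 0.36), unfolded protein response (0 and 0 of 20; 0.261), cholesterol (0 and 0 of 23; 0.755), lipid efflux (2 and 1 of 12; 0.285), oxidative phosphorylation (0 and 0 of 29; 0.285), ribosomal proteins (0 and 0 of 39; 0.755) and lysosome (1 and 1 of 30; 0.236). Apoe, a lipid carrier, was lower by -0.79 and Fas higher by 0.62. Oxidative phosphorylation and erythroid markers passed without library 12 (adjusted p = 0.0094 and 0.026). Type 1 (0 and 1 of 10), type 2 (1 and 2 of 13) and plasmacytoid dendritic cell (0 and 0 of 8), monocyte (2 and 2 of 13), B cell (1 and 0 of 7), T and NK cell (0 and 0 of 7) and erythroid markers (2 and 0 of 5) had adjusted p = 0.262, 0.71, 0.267, 0.756, 0.755, 0.36 and 0.0883. Ccl17, a chemokine for T cells, was higher by 1.08 and Blnk by 0.87. Median, mean and camera direction differed in sign for cell death (-0.01, 0.03, up), lipid efflux (0.08, -0.03, up), type 2 (-0.03, 0.02, up) and B cell markers (-0.11, 0.03, up).

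**Figure D5:**
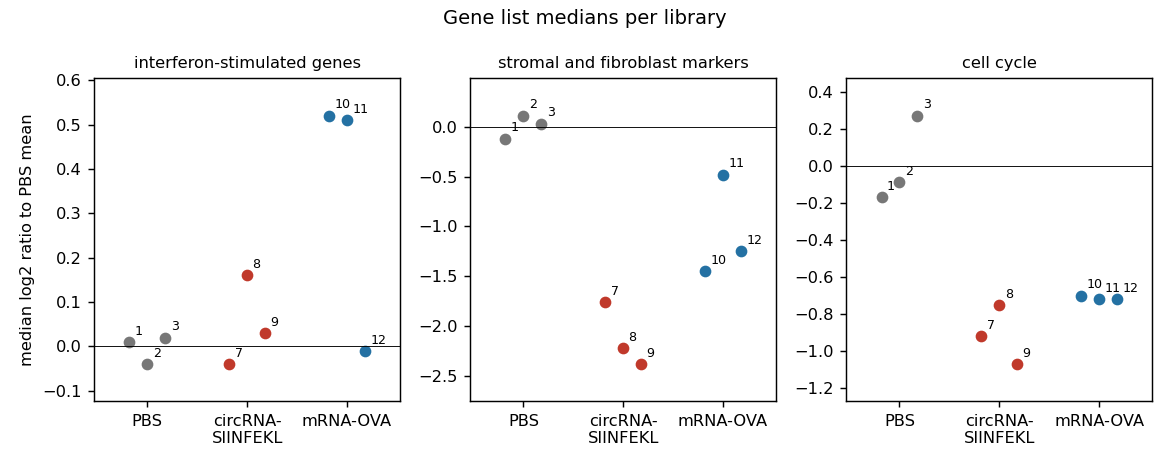
Median log2 ratio to the PBS mean of 3 gene lists in each of the 9 libraries, labelled with library numbers and coloured by group. For interferon-stimulated genes, library 12 (mRNA-OVA) was at -0.01 while libraries 10 and 11 were at 0.52 and 0.51.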

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

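The tests of the 3 patterns below were chosen after the results were seen, whereas the counts over other splits of the libraries were planned before the data were examined.

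12 genes passed the threshold in opposite directions after the RNAs, and the difference between the RNAs also passed for each, which was nearly assured by the way these genes were picked and adds little support. Rising after circRNA-SIINFEKL and falling after mRNA-OVA were Il12b (difference 2.15 ± 0.15 log2, SE), the costimulatory gene Cd40 (1.21 ± 0.14), the chemokines Ccl17 (1.08 ± 0.08), Ccl5 (0.82 ± 0.08) and Ccl22 (0.72 ± 0.07), Exoc3l4 (0.92 ± 0.13), Blnk (0.87 ± 0.12), Marcksl1 (0.71 ± 0.08) and Bcl2a1d (0.55 ± 0.07). Moving the other way were the mannose receptor Mrc1 (-1.22 ± 0.08), Ifit2 (-1.16 ± 0.19) and the lipid hydrolase Nceh1 (-0.37 ± 0.06). Against PBS the changes after circRNA-SIINFEKL were 1.31 for Il12b, 0.56 for Cd40, 0.62 for Ccl17 and -0.77 for Mrc1, and after mRNA-OVA they were -0.84, -0.65, -0.46 and 0.45. Marcksl1, Ccl22, Bcl2a1d, Ccl5, Exoc3l4 and Nceh1 were singled out after their values were seen. Some of these calls were close to the threshold, with adjusted p = 0.0484 for Nceh1 after circRNA-SIINFEKL (-0.16) and 0.0454 for Exoc3l4 after mRNA-OVA (-0.38). Ifit2 had adjusted p = 0.0445 after mRNA-OVA (0.54) and 0.024 after circRNA-SIINFEKL (-0.62).

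Interferon-stimulated genes were lower after circRNA-SIINFEKL than after mRNA-OVA, with library medians of -0.04, 0.16 and 0.03 against 0.52, 0.51 and -0.01 in libraries 10, 11 and 12. Leaving out any 1 library kept the list's adjusted p at or under 0.00052, which argues against a single library carrying the call at the preset correlation, although the median of -0.28 went to -0.15 without library 10 and to -0.43 without library 12, and members past the threshold went from 6 to 1 without library 10 or 11 and to 29 without library 12. With a correlation estimated from the data the adjusted p was 0.51, and library 12 lay among the circRNA-SIINFEKL libraries. A list that swings together from library to library therefore cannot be told apart from an effect of the RNA, given this overlap. The form of the RNA and its antigen stay open as untested biological explanations.

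Stromal genes were lower after circRNA-SIINFEKL than after mRNA-OVA (median -1.28, adjusted p = 0.14 with an estimated correlation). A loss of stromal cells with all their RNA in proportion would move the abundant members alike, provided that no other cells expressed them. Among Col1a1, Col1a2, Col3a1, Sparc, Acta2 and Tagln the differences were unequal. The highest p of Cochran's Q was 8.5e-06 over all fits that left out 1 library. Acta2 differed by -0.05 ± 0.11 and Col1a2 by -1.28 ± 0.19. Acta2 stood at 8.92 to 10.2 CPM after circRNA-SIINFEKL and 9.57 to 10.4 after mRNA-OVA, against 36.7 to 45.3 in PBS. Expression in other cells was not measured, so the unequal differences do not decide against a loss of stromal cells. Without library 11 the median was -0.67, and the members past the threshold went from 7 to 3. Libraries 10 and 12, at medians of -1.45 and -1.25 against the PBS mean, still lay above the circRNA-SIINFEKL libraries (-1.76, -2.22 and -2.38). Library 11 alone therefore does not account for the whole difference. Whether the rest exceeds the spread among libraries cannot be told, as the list was not called with an estimated correlation. A change in stromal gene expression, a change in cell number or both may explain the pattern, and the RNA itself stays open and untested.

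Cell cycle genes were lower after both RNAs, in 3 of 3 libraries of each group, but neither call held with an estimated correlation (adjusted p = 0.17 in both). An error of scaling would move all genes alike, and is argued against by a cell cycle median that differed from that of all genes by -0.76 after mRNA-OVA. A loss of stromal cells that carried this RNA could explain it: from the falls after circRNA-SIINFEKL it predicts a median of -0.52 after mRNA-OVA, and the observed -0.76 differed by -0.24 with a jackknife SE of 0.17, within the bound of 2 SE, itself set after the result was seen. The prediction takes the stromal falls as a proportional loss, which the unequal stromal differences between the RNAs leave in doubt. It also needs stromal cells to have held 60.6% of the cell cycle RNA in PBS (52.2% to 64.4% with 1 library left out). That share was not measured. The prediction therefore decides nothing, and loss of stromal cells cannot be told apart from a lower rate of division. Mpo, a gene of early granulocyte precursors, fell as well (-1.97 and -1.43), and a loss of such cells and an effect of the RNA stay open and untested.

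For each comparison the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For circRNA-SIINFEKL against PBS the real split gave 4938 genes and the highest other 0 by edgeR, with 1 split reaching the real value. For mRNA-OVA against PBS the values were 3861, 0 and 1. For circRNA-SIINFEKL against mRNA-OVA they were 861, 1 and 1.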

How the results depend on the processing

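Only the totals of the authors' filtered table were added after the data were seen. With 3 against 3 libraries the exact permutation p cannot go under 0.1, so they say nothing about the stability of that result. No paired analysis was possible because the columns carry only running library numbers, which are not the replicate numbers of the labels, and matching them by their order would be a guess, so the fits with a replicate block set out beforehand were not run.

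Across DESeq2, library totals and each library left out, 276 results for named genes gave 3036 values. Of these 2874 stayed on their side of the threshold, 146 lost their call and 16 gained one. None of the called ones reversed, while some uncalled ones changed sign, such as Actb with library totals. For the gene lists, library totals, the estimated correlation, fry and each library left out gave 1080 values for 90 results. Of these 997 stayed on their side, 70 lost the call and 13 gained it. The estimated correlation accounted for 35 of the lost calls and fry for 8. None of the called lists reversed, while medians of some uncalled lists changed sign with library totals.

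An estimated correlation left 4, 2 and 3 lists called for circRNA-SIINFEKL against PBS, mRNA-OVA against PBS and circRNA-SIINFEKL against mRNA-OVA, against 13, 18 and 13 with the preset one. Fry called 16, 19 and 8, with 7 higher and 1 lower in the last comparison against 6 and 7 by camera. Against camera at the preset correlation, fry gained 7 list calls and lost 8. The lost ones included interferon-stimulated genes after mRNA-OVA (fry adjusted p = 0.18) and between the RNAs (0.23). Between the RNAs, guanylate-binding proteins with immunity-related GTPases, cell cycle, macrophage, neutrophil and mast cell lists were also lost (0.083, 0.29, 0.083, 0.58 and 0.23). A correlation above the preset 0.01 widens the camera test by construction. In circRNA-SIINFEKL against PBS the estimate was 0.78 for cell cycle but -0.031 for cell death effectors, and both calls ended. In that comparison T and NK cell markers, at an estimate of -0.0049, also lost their call, while the integrated stress response, at -0.0042, kept it. A call lost with an estimated correlation therefore does not by itself show that the members vary together. What else ended calls was not tested. Fry asks a different question from camera, and the cause of its differences was not tested. At a fold change of at least 2, 390 genes were called in both treatments against PBS in the same direction instead of 3069, by construction. With all tested genes the first component held 46.1% of the variance instead of 55.5%, since less variable genes entered.

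Leaving out 1 library at a time, genes called between the RNAs ranged from 490 (without library 9) to 959 (without library 1), and the first component from 50.6% (without library 3) to 61.5% (without library 11). The cause was not tested. Genes called ranged from 3966 to 4864 for circRNA-SIINFEKL against PBS and from 2950 to 3906 for mRNA-OVA against PBS. Where these fits left 2 libraries in a group, the spread was pooled over the groups.

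DESeq2 called 4635, 3614 and 955 genes in the 3 comparisons. Library totals called 6053, 4647 and 927, with 26.8%, 29.2% and 49.2% of them higher instead of 51.9%, 54.7% and 58.7%, so the balance of rises and falls depends on the scaling. Without a filter on low counts, 1252 genes were called between the RNAs, and with a filter at 10 CPM, 775.

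Depth limits genes near the floor. Interferon genes, with at most 3 counts in any library, could not be tested, and Csf3 had no count in PBS.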

Other observations

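All 5 gene lists in this part were chosen after the data were seen, and their adjusted p-values cover these 5 lists alone, so the results are hypotheses.

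Oxidative stress genes under the transcription factor NRF2 were higher after circRNA-SIINFEKL (24 of 26 genes, median log2 fold change 1) and after mRNA-OVA (21 of 26, median 0.53), with adjusted p = 0.0069 and 0.031 with an estimated correlation. Between the RNAs 18 were higher after circRNA-SIINFEKL (median 0.45, adjusted p = 0.026 with an estimated correlation). Hmox1, which degrades heme, was at 2.15 and 0.97 after circRNA-SIINFEKL and mRNA-OVA, Prdx1, a peroxidase, at 2.06 and 1.08, and Nqo1, a quinone reductase, at 2.01 and 1.02.

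Matrix metalloproteinase and plasminogen system genes had 13 higher and 4 lower of 20 after circRNA-SIINFEKL and 12 and 2 after mRNA-OVA, with adjusted p = 0.061 and 0.041 with an estimated correlation. The collagenase Mmp13 was at 1.69 and 1.60 and the elastase Mmp12 at 1.48 and 1.28.

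Immediate early genes had 11 higher and 3 lower of 20 after circRNA-SIINFEKL and 10 and 3 after mRNA-OVA, with adjusted p = 0.0069 and 0.0072 with an estimated correlation. Fos was at 1.33 and 1.26, Egr1 at 1.15 and 1.37, and Nr4a3 at -0.61 and -0.78.

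Granulocyte genes were divided into early and late lists, and no test compared the lists. Early granule genes had 0 higher and 4 lower of 7 after circRNA-SIINFEKL and 1 and 4 after mRNA-OVA, with Elane at -1.19 and -0.84. Late granule genes had 9 higher and 1 lower of 12 and 10 and 0, with Ngp at 0.62 and 0.74. With an estimated correlation none of these 4 results was called (adjusted p = 0.14, 0.18, 0.25 and 0.13).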
